A study of Homo sapiens with 4 samples.

How the data were processed

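The data were RNA-seq libraries of DBTRG-05MG cells, an established human glioblastoma line, carrying either a scramble control shRNA (sh-NC) or an shRNA against POLR2B (sh-POLR2B). Each group had 2 libraries. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with the Illumina TruSeq RNA kit, and the series' design text names the NovaSeq6000 as the instrument. This kit selects polyadenylated RNA and does not mark the strand, so reads of overlapping genes on opposite strands cannot be told apart. Nothing in the labels says that libraries of a group came from separate cultures. The p-values therefore measure the spread between these samples, which may be technical.

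Per the submitters' processing notes, HISAT2 2.2.0 and genome build hg38 were used. The counting tool, the gene annotation and the method of scaling are not given in the sources used here. The authors deposited 1 table of 20308 Ensembl gene IDs by 4 libraries, and its values are a normalised signal, read from the values themselves as estimated read counts divided by 1 size factor per library. In each library a large share of genes had values that were whole multiples of 1 step, between 86.8% and 87.4% of the genes tested with a tolerance of 0.02 reads, and 81.7% were whole in all 4 libraries. The rest were fractional, with some values far below 1 read, so whole reads were not recovered for nearly all genes and count models were not run. The steps gave an estimated 13756021 and 14263088 reads for the sh-NC libraries and 11905739 and 12240892 for the sh-POLR2B libraries. Depth at this level leaves genes with values near the minimum imprecise. Fractional genes may share reads with other genes, which the table does not record.

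Symbols came from a table of gene names, which held 19434 of the IDs, and coordinates from GENCODE release 29 on GRCh38, the same assembly as hg38, which held 19499. GC content and length came from 1 transcript per gene, the longest protein-coding transcript where there was one, for 19498 IDs and for 98.9% of the genes tested. Exons of 25 of the 98 named genes overlap an exon of another protein-coding gene in that annotation.

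Genes were kept with a value of at least 10 in at least 2 of the 4 libraries, which left 12694. Values were transformed as log2(value + 1), so a fold change is on that scale and understates the change of low genes. The groups were compared with limma 3.58.1 in R 4.3.3 (linear model per gene, empirical Bayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment over all kept genes and a threshold of 0.05. POLR2B was a single planned test and is reported with its own p beside the adjusted one. A permutation of the 4 libraries cannot give a two-sided p under 0.333. Gene lists were compared with all other genes by limma's camera with a preset correlation between genes of 0.01, adjusted over 33 lists. Of the 34 lists written, the endothelial marker list had fewer than 5 kept genes. Camera with an estimated correlation, and fry, which tests whether a list's genes move on balance 1 way without comparing them with other genes, were run beside it. With an estimated correlation camera also has only the 2 residual degrees of freedom of the fit. A call lost there therefore need not mean that the genes of the list are correlated.

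The groups, tests, lists, rule for named genes and most alternatives were set before the data were examined. The alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 100 in all libraries, quantile normalisation, scaling by median ratios, no mean-variance trend, robust empirical Bayes, the replicate number as a block, and leaving out each library in turn. Planned count models were not run, for the reason above. After the data were seen, a correction was added that removes from each library a smooth trend (splines with 5 degrees of freedom) on transcript GC content and log2 length, for 12556 genes, alone and with the block, and a fit on genes with whole values in all libraries. Corrected values are called corrected. List results are given beside the deposited ones, but the corrected changes of some single genes stand alone.

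The rule for named genes took POLR2B and the other RNA polymerase II subunits. It also took up to 4 members with the lowest p of each list past its threshold and of a fixed set of lists. Since fewer than 5 genes passed the adjustment, the 10 genes with the lowest unadjusted p in each direction were taken as well. The rule left open whether its conditions on expression level, gene name and separation of the groups hold in that last case, so both readings were taken, without and with those conditions. Some of the named genes and 1 gene list, which is among the 4 that passed as higher in camera with deposited values, are not reported here. A few genes outside the rule are named as such where they appear.

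The fit was tested on simulated counts for the sh-POLR2B and sh-NC comparison, drawn with the spread of the sh-NC pair. Among 12428 genes it called 98% of 100 genes changed 2-fold and 100% of 100 changed 4-fold, and 0 unchanged genes. With the GC and length trends of the 4 libraries added, it called 0% at either size among 12440 genes. After the correction it called 100% at both sizes, with 12 unchanged genes called. The added trends came from the same splines that the correction removes, so their removal was fixed in advance. In the real data the corrected interquartile range of the sh-POLR2B pair was still 1.98 times that of sh-NC. The simulation therefore does not give the share of changed genes that the fit would find in the real libraries.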

Results

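RNA-seq profiles of DBTRG-05MG, a human glioblastoma line, were compared between 2 libraries with a scramble shRNA (sh-NC) and 2 libraries with an shRNA against POLR2B (sh-POLR2B). POLR2B encodes the second-largest subunit of RNA polymerase II, the enzyme that transcribes messenger RNA. The series title names POLR2B as a regulator of growth in glioblastoma, and the comparison asks which transcripts differ when its mRNA is lowered. Values are normalised read counts as deposited, with similar totals in all libraries (12952491 to 13123460). A rise or fall is therefore relative to the other genes, and a change in the total amount of mRNA would not be seen. Estimated depth was 13756021 and 14263088 reads for sh-NC and 11905739 and 12240892 for sh-POLR2B, and 12694 genes were tested.

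POLR2B mRNA (ENSG00000047315, hg38 chromosome 4, 56977722 to 57031168, plus strand) fell in both sh-POLR2B libraries. Its normalised count was 1382 ± 62.4 (SD, n = 2) in sh-NC and 495 ± 166 (SD, n = 2) in sh-POLR2B, where the libraries held 378 and 612, or 27.3% and 44.3% of the sh-NC mean. The log2 change was -1.52 with a standard error of 0.29, a fold of 0.349. As the single planned test it gave p = 0.00294 in limma, where a permutation of the libraries could not go below 0.333, and the Benjamini-Hochberg adjusted p over all genes was 1.00. After the GC and length correction it was -1.59, with the lowest p of the 12556 genes fitted (4.99e-05, adjusted p = 0.293). Its exons share 251 bases with NOA1 and 270 with IGFBP7 on the opposite strand.

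The other 12 RNA polymerase II genes did not pass the adjustment over all genes. POLR2A, the largest subunit, had 2419 ± 57.2 normalised counts in sh-NC and 3736 ± 63.9 in sh-POLR2B (SD, n = 2 each), a log2 difference of 0.63 with a standard error of 0.18 (limma adjusted p = 1.00). It was higher in both sh-POLR2B libraries than in either sh-NC library, and after correction it passed with adjustment over the list alone (adjusted p = 0.0165). POLR2C was at 1617 ± 51.4 and 1754 ± 12.8, and POLR2D at 472 ± 30.4 and 489 ± 17.9 (SD, n = 2 each). For POLR2L the sh-POLR2B libraries lay on either side of sh-NC, at 2213 ± 1194 against 1744 ± 104 (SD, n = 2 each). The list median was -0.04 and did not pass in camera (adjusted p = 0.38), with opposite medians of 0.24 and -0.28 in sh-POLR2B replicates 1 and 2. The corrected median was 0.08 and passed (adjusted p = 0.0259, or adjusted p = 0.396 with an estimated correlation), with 0.18 and 0.04 in those libraries. Subunits of RNA polymerases I and III, 19 genes, had a median of 0.01 (adjusted p = 0.883), with POLR3E at -0.35 and POLR1C at 0.26.

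**Figure D1:**
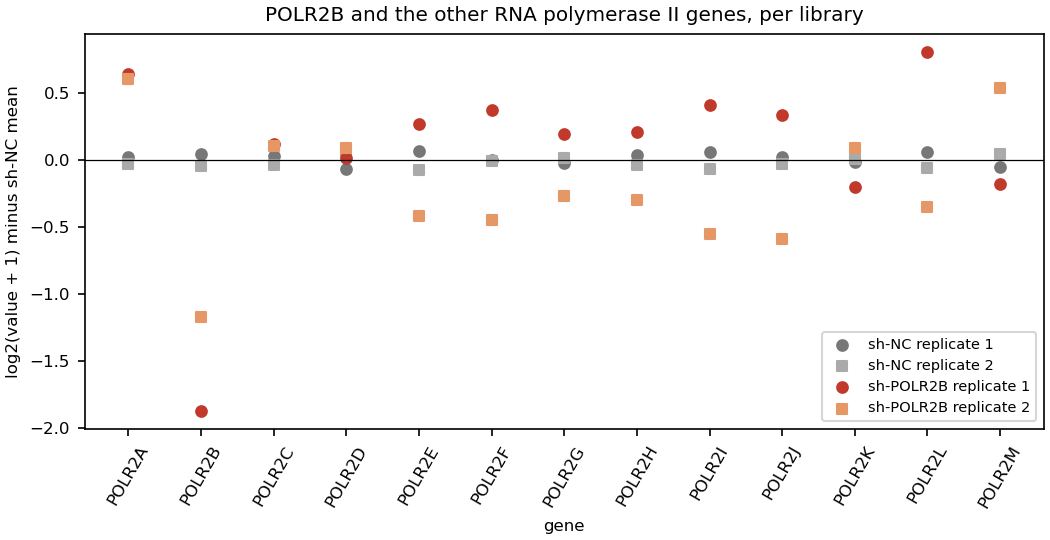
Log2(value + 1) of POLR2B and the other RNA polymerase II genes in each library, minus the sh-NC mean of the gene; circles are replicate 1 and squares replicate 2, grey for sh-NC and red or orange for sh-POLR2B. POLR2B lies below sh-NC in both sh-POLR2B libraries and POLR2A above, while POLR2L and several others lie on opposite sides of it.

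In limma 0 of 12694 genes passed an adjusted p of 0.05 (lowest adjusted p = 1.00), and 224 had an unadjusted p under 0.05, 96 higher and 128 lower, where chance gives 635. Leaving out sh-POLR2B replicate 1 gave 3815 calls, replicate 2 gave 1893, sh-NC replicate 1 gave 14 and sh-NC replicate 2 gave 10. In those fits the lone library is assumed to vary like the other group. Groups did not overlap for 1438 genes higher and 1550 lower in sh-POLR2B, together 23.5% of genes, where chance gives 33.3%.

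The sh-POLR2B libraries differed from each other more than from sh-NC. The interquartile range of their log2 difference across genes was 1.07, against 0.319 for the sh-NC pair, and their correlation across genes was 0.931, against 0.980, and 0.949 to 0.975 between libraries of different groups. The first principal component, 63.6% of the variance, set the sh-POLR2B libraries apart from each other, and the second, 22.3%, separated sh-POLR2B from sh-NC. The sh-POLR2B pair difference followed transcript composition. It had a median of -1.11 in the lowest of 10 equal groups of genes by GC content (up to 38.6%) and 0.53 in the highest (from 61.9%), against -0.25 and 0.16 for the sh-NC pair. GC content and length together accounted for 49.96% of its variance across genes, for 9.05% in the sh-NC pair and for 4.72% of the difference between groups. After correction the interquartile ranges were 0.505 and 0.256, and 0 of 12556 genes passed in limma (lowest adjusted p = 0.293), with 923 at an unadjusted p under 0.05, 400 higher and 523 lower, where chance gives 628.

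**Figure D2:**
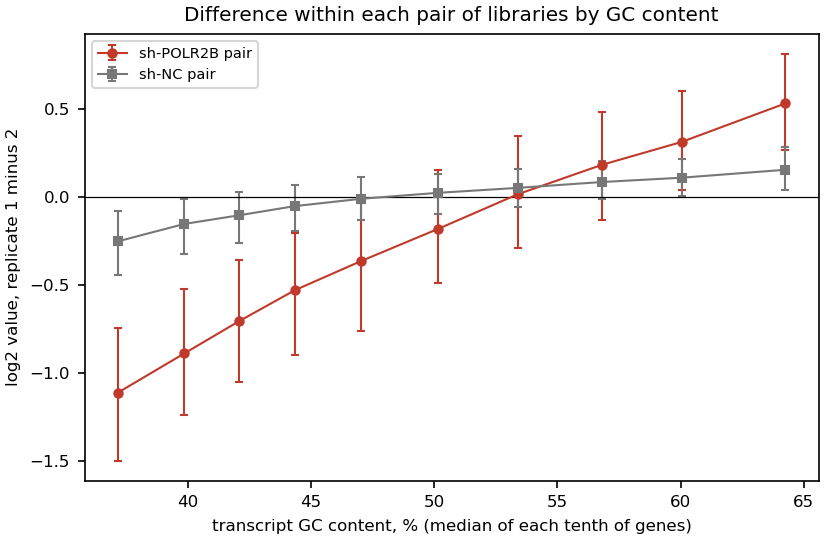
Median log2 difference between replicate 1 and replicate 2 within each group, over 10 equal groups of genes by transcript GC content in percent; bars span the quartiles of the genes in a group. The sh-POLR2B pair runs from -1.11 to 0.53 and the sh-NC pair from -0.25 to 0.16.

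Genes with the lowest p in the lower direction included several of amino acid supply and stress signalling, none past the adjustment over all genes. ASNS (ENSG00000070669), asparagine synthetase, had 2051 ± 102 normalised counts in sh-NC and 864 ± 28.0 in sh-POLR2B (SD, n = 2 each), a fold of 0.421 (limma adjusted p = 1.00). DDIT4, an inhibitor of mTORC1 signalling, had 1051 ± 16.9 and 446 ± 14.5, a fold of 0.424. CHAC1, which degrades glutathione, had a fold of 0.312, and TRIB3, a pseudokinase induced by ATF4, a fold of 0.435. SLC7A5, a transporter of large neutral amino acids, had a fold of 0.54. Others were PIPOX, a peroxisomal oxidase of pipecolic acid and sarcosine (fold 0.463), ANPEP, aminopeptidase N (0.481), PMEPA1, a TGF-beta target that restrains its signalling (0.565), and PBRM1, a chromatin remodelling subunit (0.504). Among weakly expressed genes, DSP, desmoplakin, was at 74.3 ± 23.7 and 3.78 ± 0.803, PRND at 58.2 ± 2.18 and 12.96 ± 0.134, and SBSN at 29.9 ± 11.3 against values listed at 0 in both sh-POLR2B libraries (SD, n = 2 each).

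On the higher side, well-expressed genes with the lowest p included ACTA2, smooth muscle actin, with 689 ± 0.858 in sh-NC and 1401 ± 282 in sh-POLR2B, and TAGLN, an actin-binding protein of smooth muscle, with 1264 ± 3.94 and 2280 ± 573 (SD, n = 2 each). TPM1, a tropomyosin, had a fold of 1.49, SNRPA1, a protein of the U2 snRNP, 1.69, HSPG2, perlecan, 1.56, the taurine transporter SLC6A6 2.63, TRIM16 1.63, and TNFRSF10D, a decoy receptor for TRAIL, 1.58. None passed the adjustment over all genes, and exons of TAGLN, HSPG2, SLC6A6 and TRIM16 overlap those of another gene. IGFBP5, an IGF-binding protein, had 63.8 ± 2.32 and 203 ± 53.6, a fold of 3.10. The lowest p values on this side belonged to genes near 0 in sh-NC. These were ZBTB10 at 0.0138 against 83.9 ± 56.6, COL24A1 at 0.501 against 56.2 ± 38.1, FAM86B1 at 0.0121 against 22.1 ± 2.05, MYLK2 at 0.000643 against 16.8 ± 3.99 and STX17 at 0.582 against 22.8 ± 4.63 (mean ± SD, n = 2 each). SEZ6 was also near 0, at 0.457 against 13.5 ± 0.903, with a higher p than IGFBP5, KBTBD4 and ENSG00000188474. KBTBD4 was at 41.8 ± 36.5 and 421 ± 156, and ENSG00000188474 at 18.1 ± 13.5 and 143 ± 23.2. With a tolerance of 0.02 reads, values of ZBTB10, COL24A1, STX17, KBTBD4 and ENSG00000188474 were fractional in at least 1 library, and those of FAM86B1, MYLK2, SEZ6, SBSN, DSP and PRND were whole in all 4. FAM86B1 belongs to a family of near-identical copies, so its count is uncertain.

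Of 33 gene lists, 11 passed an adjusted p of 0.05 in camera, 7 lower and 4 higher in sh-POLR2B. With an estimated correlation 0 passed (lowest adjusted p = 0.302), and with fry 0 passed (lowest adjusted p = 0.0811), each having 4 lists at an unadjusted p under 0.05. No member of any list passed the adjustment over all genes. After correction 13 lists passed, 10 of them shared with the 11, and 0 with an estimated correlation (lowest adjusted p = 0.203). Without sh-POLR2B replicate 1 the count was 7, and without replicate 2 it was 16.

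The integrated stress and unfolded protein response list fell as a group. Its 38 genes had a median log2 difference of -0.24 (camera adjusted p = 1.32e-10, or adjusted p = 0.302 with an estimated correlation), at -0.36 in sh-POLR2B replicate 1 and -0.34 in replicate 2, and -0.42 among genes with whole values. Of the members 25 were negative and 13 positive, and 20 lay below sh-NC in both sh-POLR2B libraries. Adjusted over the list alone, 2 members passed, ASNS (adjusted p = 0.0382) and CHAC1 (adjusted p = 0.0412). After correction the median was -0.20 (camera adjusted p = 1.61e-08, or adjusted p = 0.203 with an estimated correlation), and 14 members were lower and 1 higher adjusted over the list alone. The 14 include ATF4, the transcription factor of the integrated stress response (corrected log2 change -0.55 ± 0.09 SE), its partner DDIT3 (-0.65 ± 0.11), the serine synthesis enzymes PHGDH (-0.66 ± 0.13) and PSAT1 (-0.87 ± 0.13), CTH (-1.22 ± 0.21), and XBP1 (-0.68 ± 0.14) and HERPUD1 (-0.60 ± 0.10) of the endoplasmic reticulum response. ATF5 was the 1 higher member (0.64 ± 0.15). The chaperones HSPA5 and HSP90B1 had deposited differences of -0.09 ± 0.17 and 0.13 ± 0.17 (SE).

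**Figure D3:**
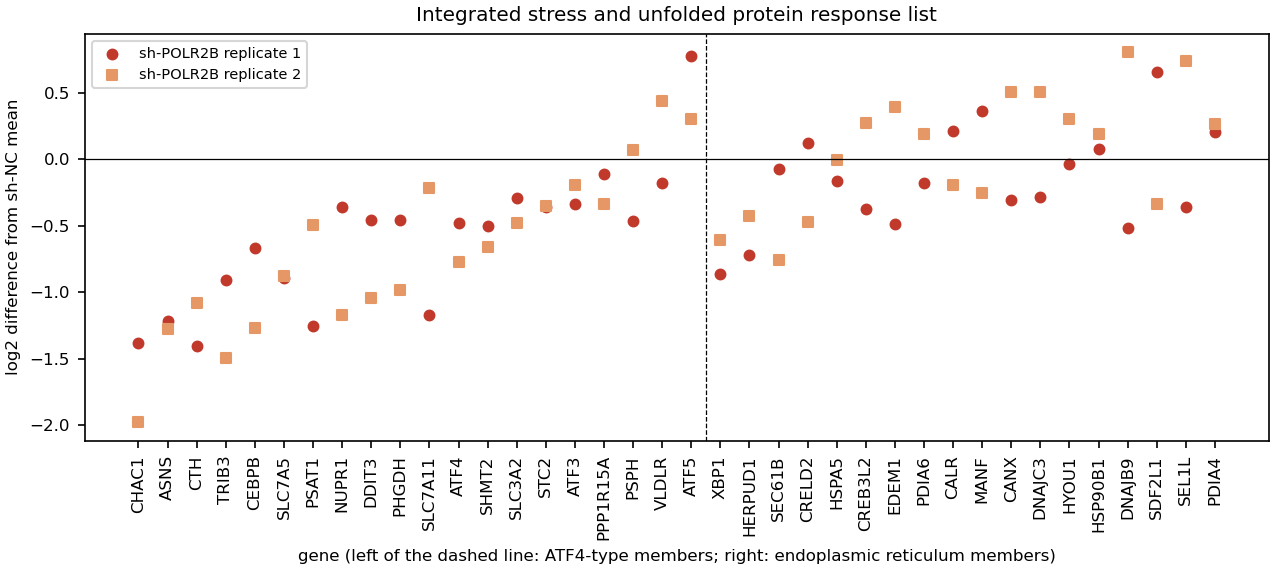
Log2 difference of each member of the integrated stress and unfolded protein response list from the sh-NC mean, in sh-POLR2B replicate 1 (circles) and replicate 2 (squares), with amino acid and ATF4-type genes left of the dashed line and endoplasmic reticulum genes right of it. ASNS, CHAC1 and TRIB3 lie below 0 in both libraries, and HSPA5 and HSP90B1 lie near it.

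Genes of glycolysis and hypoxia, 43 measured, fell as a group with a median of -0.23 (camera adjusted p = 1.27e-06, or adjusted p = 0.302 with an estimated correlation). The medians were -0.27 and -0.18 in the sh-POLR2B libraries, and 36 members were negative. None passed adjusted over the list alone, and after correction 5 did, all lower. These were DDIT4, VEGFA, the angiogenic growth factor (corrected log2 change -0.91 ± 0.18 SE), BNIP3L, a mitophagy receptor (-0.57 ± 0.10), LOX, which crosslinks collagen (-0.64 ± 0.13), and PDK1, which restrains pyruvate oxidation (-0.63 ± 0.14). As deposited, BNIP3L, LOX and PDK1 were at -0.51 ± 0.37, -0.54 ± 0.39 and -0.50 ± 0.38 (SE). Their values in sh-POLR2B replicate 2 (1134, 497 and 372) lay within the sh-NC range, and only replicate 1 was below it. CA9, a carbonic anhydrase induced in hypoxia, was at 41.7 ± 1.42 and 14.8 ± 2.70, and the enolase ENO2 at 3026 ± 105 and 2333 ± 99.8 (SD, n = 2 each).

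Both cell cycle lists fell in camera, G2/M and mitosis with a median of -0.25 over 69 genes (adjusted p = 1.32e-10, or adjusted p = 0.639 with an estimated correlation) and G1/S and DNA replication with -0.12 over 63 genes (adjusted p = 0.00235, or adjusted p = 0.761 with an estimated correlation). Negative members numbered 59 and 49, and none passed adjusted over the list alone. PLK1, a mitotic kinase, was at 2231 ± 91.8 in sh-NC and 1535 ± 127 in sh-POLR2B, CIT, citron kinase, at 871 ± 27.3 and 531 ± 21.99, and cyclin B2, CCNB2, at 2033 ± 70.2 and 1470 ± 22.1 (SD, n = 2 each). RRM2, a ribonucleotide reductase subunit, had a fold of 0.772 and the helicase subunit MCM7 0.791. The G2/M median was -0.46 in sh-POLR2B replicate 1 and 0.07 in replicate 2, and the G1/S median -0.20 and 0.08. Without replicate 1 the camera adjusted p was 0.162 and 0.432. The G1/S call was also lost without sh-NC replicate 2, at a median of -0.13 (adjusted p = 0.0952). After correction the G2/M medians were -0.29 and -0.22 (list adjusted p = 4.94e-16, or adjusted p = 0.203 with an estimated correlation), and those of G1/S -0.10 and -0.11 (adjusted p = 0.000586, or adjusted p = 0.203 with an estimated correlation).

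Apoptosis regulators, 35 genes, did not pass (median 0.08, adjusted p = 0.364), with BIRC5, survivin, at a fold of 0.795 and TNFRSF10B, a TRAIL death receptor, at 1.22. Growth factor receptors and downstream kinases did not pass either (46 genes, median 0.08, adjusted p = 0.354). Their medians were -0.25 and 0.30 in the sh-POLR2B libraries, and AXL, a receptor tyrosine kinase, was at 5868 ± 154 and 3968 ± 342 (SD, n = 2 each).

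Replication-dependent histone genes rose, with all 10 members that passed the minimum value positive, of 23 in the table, and a median of 0.71, a fold of 1.64 (camera adjusted p = 1.67e-07, or adjusted p = 0.302 with an estimated correlation). H2BC12 was at 119 ± 3.11 in sh-NC and 299 ± 39.8 in sh-POLR2B (SD, n = 2 each) and passed adjusted over the list alone (adjusted p = 0.0433). With no minimum value the list median was 0.47 (camera adjusted p = 0.00344). H2BC5 had a fold of 1.97 and H2AC6 1.69. These genes resemble each other in sequence, and together they made up 0.00568% and 0.00537% of sh-NC and 0.0102% and 0.00886% of sh-POLR2B signal. Because the kit selects polyadenylated RNA, histone mRNA without a poly(A) tail would not be captured. The higher values thus describe only the histone RNA that the kit captured. Type I interferon response genes rose with a median of 0.26 over 39 genes, 31 of them positive (adjusted p = 1.11e-05, or adjusted p = 0.341 with an estimated correlation). IFI6 was at 298 ± 34.1 and 709 ± 338, MX2 at 11.6 ± 0.355 and 32.4 ± 5.77, IFI44L at 18.2 ± 3.77 and 47.5 ± 8.67, and OAS1 at 73.7 ± 22.4 and 130 ± 5.17 (SD, n = 2 each). None passed adjusted over the list alone, and after correction IFI6 and IFITM3 did. Mitochondrially encoded mRNAs rose with a median of 0.29 over 11 genes (adjusted p = 8.67e-05, or adjusted p = 0.341 with an estimated correlation). They took 4.36% and 4.39% of sh-NC and 5.82% and 4.86% of sh-POLR2B signal, and MT-CYB, cytochrome b, had a fold of 1.51. After correction 8 of the 11 passed as higher adjusted over the list alone. Without sh-POLR2B replicate 1 all 3 calls were lost, at a higher median of 0.81 for histones (camera adjusted p = 0.162) and 0.54 for interferon genes (adjusted p = 0.0562) and a lower one of 0.18 for mitochondrial mRNAs (adjusted p = 0.0893). The interferon median was 0.14 without replicate 2 (adjusted p = 0.00201).

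Immediate early genes fell with a median of -0.20 over 31 genes (camera adjusted p = 0.00522, or adjusted p = 0.761 with an estimated correlation). FOSL1 was at 3500 ± 169 and 2414 ± 353 and JUN, also of the AP-1 complex, at 1618 ± 35.0 and 1123 ± 95.3 (SD, n = 2 each). The call was lost at a similar median without a filter (-0.18, adjusted p = 0.0904) and without sh-NC replicate 1 (-0.20, adjusted p = 0.0586), and at a median of 0.04 without sh-POLR2B replicate 1 (adjusted p = 0.188). It held at -0.14 without sh-NC replicate 2 (adjusted p = 0.0365). The mesenchymal-like state of glioblastoma, 23 genes, fell with a median of -0.08 and 18 negative (adjusted p = 0.00265, or adjusted p = 0.378 with an estimated correlation). VIM, vimentin, was at 91222 ± 32.4 and 62901 ± 4483, CEBPB at 695 ± 103 and 360 ± 105, and LGALS3, galectin 3, at 4345 ± 56.5 and 2811 ± 422 (SD, n = 2 each). Its median was -0.20 without sh-POLR2B replicate 2, where the call was lost (adjusted p = 0.199), -0.18 without sh-POLR2B replicate 1, -0.13 and -0.19 without sh-NC replicate 1 and 2, and -0.19 with no filter, where it held. Cytosolic ribosomal proteins, 78 genes, fell with a median of -0.11 (adjusted p = 0.00396, or adjusted p = 0.851 with an estimated correlation), but their medians were 0.25 and -0.49 in the sh-POLR2B libraries. The estimated correlation between these genes was 0.97. After correction the median was -0.03 (camera adjusted p = 0.775), with 0.21 and -0.26 in the sh-POLR2B libraries, still on opposite sides. Among genes with whole values the camera adjusted p was 0.12. Without sh-POLR2B replicate 2 the direction reversed, with a median of 0.25 that passed as higher (adjusted p = 9.33e-37).

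**Figure D4:**
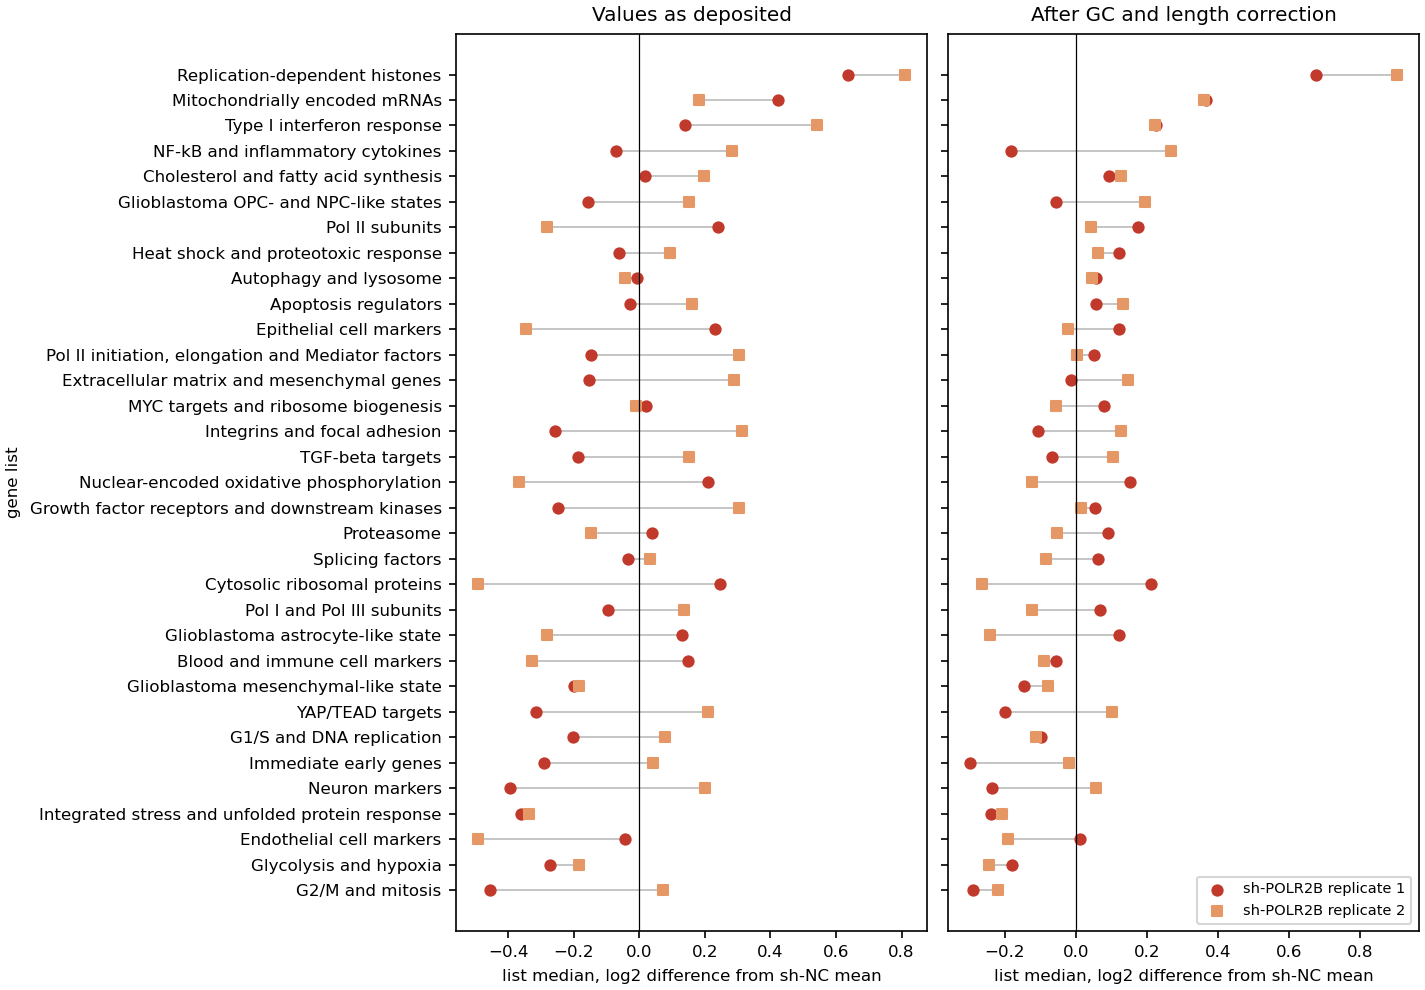
Median log2 difference of the gene lists described here from the sh-NC mean, in sh-POLR2B replicate 1 (circles) and replicate 2 (squares), from deposited values (left) and after the GC and length correction (right). The integrated stress and glycolysis lists lie below 0 and histones above 0 in both libraries and both panels, while cytosolic ribosomal proteins lie at 0.25 and -0.49 on the left.

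The other lists described here did not pass with deposited values. Nuclear-encoded oxidative phosphorylation genes had a median of -0.08 (67 genes, adjusted p = 0.159), with 0.21 and -0.37 in the sh-POLR2B libraries. Splicing factors were at -0.06 (adjusted p = 0.449), initiation, elongation and Mediator factors of RNA polymerase II at 0.07 (adjusted p = 0.299), MYC targets and ribosome biogenesis at 0.00 (adjusted p = 0.885), the proteasome at -0.04 (adjusted p = 0.567) and autophagy and lysosome genes at 0.04 (adjusted p = 0.466). Heat shock genes had a median of 0.10 (adjusted p = 0.26) and cholesterol and fatty acid synthesis 0.06 (adjusted p = 0.236), and both passed after correction (adjusted p = 0.0301 and 0.0362, each with adjusted p = 0.323 with an estimated correlation). Matrix and mesenchymal genes (median 0.04, adjusted p = 0.622), integrins and focal adhesion (0.06, 0.883), YAP/TEAD targets (-0.01, 0.26), inflammatory cytokines (0.14, 0.883) and TGF-beta targets (0.00, 0.373) did not pass. Nor did the astrocyte-like (-0.03, 0.26) or the progenitor-like glioblastoma states (0.10, 0.354). Markers of other cell types were scarce. Neuronal markers took at most 0.0078% of the signal in any library, blood and immune markers 0.00496%, endothelial markers 0.0014% and epithelial markers 0.0434%. Neuronal (adjusted p = 0.299), blood (adjusted p = 0.244) and epithelial lists (adjusted p = 0.26) did not pass in camera.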

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

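The GC and length correction, alone and with the block, and the fit on genes with whole values were chosen after the data were seen. The POLR2B result kept its direction and its p under 0.05 in all 16 alternatives, with a log2 change from -1.87 to -1.17 and p from 3.58e-13 to 0.0184. The count of 0 genes, with or without a 2-fold criterion, held under pseudocounts, filters, scalings, variance models, the correction with and without the block, and whole-value genes. With the replicate block it became 37, and 37 with the 2-fold criterion. The replicate numbers share only a number, since the labels name no common batch, and same-numbered deviations correlated at 0.272 across genes, or 0.140 after correction. The block left the lists at 11 and the correction with the block gave 12. Leaving out 1 library gave between 10 and 3815 genes, between 10 and 803 with 2-fold, and between 7 and 16 lists, with the lone library assumed to vary like the other group; the cause was not tested. The lists fell from 11 to 0 with an estimated correlation and to 0 with fry. The integrated stress and the glycolysis lists stayed past the threshold in all 16 settings that kept the preset correlation. Leaving out an sh-POLR2B library reversed directions. The genes and lists named first are those that also passed the threshold when reversed. Over the libraries left out, log2 changes ran from -0.35 to 0.81 for POLR2L and from -0.44 to 0.37 for POLR2F, and medians from -0.49 to 0.25 for cytosolic ribosomal proteins, -0.37 to 0.21 for oxidative phosphorylation, -0.26 to 0.31 for integrins and -0.15 to 0.038 for the proteasome. Others changed sign too, such as POLR2I from -0.55 to 0.41 and the matrix and mesenchymal list from -0.15 to 0.29. The cause was not tested. Of 1515 values of named genes over the alternatives, 1362 kept their side of the threshold, 151 newly passed in the same direction and 2 passed in the reverse direction. Direction was not counted among the 1362, which include changes of sign. POLR2J, for example, was at -0.13 as deposited and 0.02 after correction. The planned count models were not run. Depth limits genes near the minimum value, where a few reads decide the fold.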

Other observations

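Within lists that did not pass as a whole, members went opposite ways. Among inflammatory cytokines, the neutrophil chemokine CXCL8 was at 395 ± 17.4 in sh-NC and 158 ± 75.5 in sh-POLR2B and CXCL1 at 284 ± 51.8 and 106 ± 24.9, while the monocyte chemokine CCL2 was at 36.7 ± 8.92 and 81.0 ± 8.48 (SD, n = 2 each). None of them passed adjusted over the list alone with deposited values, and all 3 did after the GC and length correction in limma (adjusted p = 0.0102, 0.0452 and 0.0452). Of the TGF-beta targets, PMEPA1 and NOG, an antagonist of BMP, were lower adjusted over the list alone with deposited values (adjusted p = 0.0452 each), and ID3, a BMP-responsive gene, had a corrected log2 change of 0.68 ± 0.09 SE (adjusted over the list alone, adjusted p = 0.0052). In the matrix list, ACTA2 and TAGLN were higher and COL7A1, LOX, LOXL2, SERPINE2, VIM and TIMP3 lower after correction, each adjusted over the list alone. As deposited, LOX in sh-POLR2B replicate 2 (497) lay within the sh-NC range. The genes of these lists were picked because they passed, and none passes over all genes.

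The tests below of 1 change at different strengths, of 1 library alone, of the change removed from the stress list, of branches of the stress list, of tRNA synthetases, of contractile genes, of whole values among genes near 0 and of other splits were chosen after the results were seen, as was the correction.

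The sh-POLR2B libraries stand apart from each other more than the sh-NC libraries do. Reads divided unstably between similar genes would spare genes with whole values in all libraries, yet there the sh-POLR2B interquartile range was 3.29 times that of sh-NC. A GC and length trend of the kind that arises in library preparation may account for much of it: the regression across genes gave an R2 of 0.4996, just short of the 0.5 set beforehand as its mark, and the corrected ratio of ranges was still 1.98. A common change present at different strengths is argued against as the main cause, since it would leave both sh-POLR2B libraries on the same side of sh-NC. On the line through them over all genes (0 at replicate 2 and 1 at replicate 1) the sh-NC libraries lay between, at 0.664 and 0.529 as deposited and 0.630 and 0.529 after correction. The changes from the sh-NC library of the same number correlated at -0.0674 as deposited and 0.106 after correction. The corrected value met neither the mark for this cause nor the mark against it. On the second principal component both sh-POLR2B libraries lay on the same side of sh-NC, at -26.1 and -15.7 against 15.3 and 26.5. A lesser change shared at different strengths therefore stays open. A different effect of the knockdown in each library, with POLR2B at 27.3% and 44.3% of sh-NC, was not tested.

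The integrated stress list was lower in sh-POLR2B. A single aberrant sh-POLR2B library is argued against, because the list median was negative in all 4 pairs of an sh-POLR2B and an sh-NC library, the highest being -0.27. The GC and length trend is argued against as the whole cause: the correction removed a median of -0.0147 from the members (quartiles -0.0755 and 0.0507) of a change of -0.244, and the list stayed past its threshold (camera adjusted p = 1.61e-08). The corrected median of -0.199 lay just short of the -0.2 set beforehand as the bound for this, and with an estimated correlation the list passed neither before (adjusted p = 0.302) nor after (adjusted p = 0.203). An effect of lowered POLR2B on this pathway, or a difference in culture such as amino acid supply between the dishes, may each be behind it, and neither was tested.

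Within that list a hypothesis is that the ATF4-type members moved rather than the endoplasmic reticulum members. A split of genes by type cannot tell whether a change in ATF4 came from amino acid supply or from the endoplasmic reticulum. The 20 ATF4-type members had a median of -0.71 and the 18 endoplasmic reticulum members 0.03, a difference larger than in nearly all of 100000 permutations of the genes (permutation p = 0.00033, two-sided), although XBP1 and HERPUD1 of the latter were also low. The split was prompted by ASNS, CHAC1, TRIB3 and SLC7A5, already seen among the lower genes, so that p partly restates them. With these 4 left out, the other 16 had a median of -0.61 (permutation p = 0.00134, two-sided, and 0.00225 after correction). Several of the 16, such as ATF4, DDIT3 and PSAT1, had also been seen as lower, so this p too partly restates known values. As genes outside the list, 13 aminoacyl-tRNA synthetases known as ATF4 targets had a median of -0.40 and 7 other cytosolic synthetases 0.02 (permutation p = 0.0187, two-sided). The targets ranged from a fold of 0.645 (GARS1) to 1.08 (LARS1), with 7 of the 13 below sh-NC in both sh-POLR2B libraries and 6 overlapping it. The others ranged from 0.879 (QARS1) to 1.15 (HARS1), with 6 of the 7 overlapping sh-NC and 1 higher. After correction the permutation p values for all 20 members and for the synthetases were 0.00022 and 0.0153. Genes are not independent replicates, so these p values describe the genes and not further samples, and the result is consistent with lower ATF4 activity in these sh-POLR2B libraries without showing it.

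Some genes were near 0 in 1 group and at 10 or more in the other. There were 8 of them, SEZ6, MYLK2, PADI4, COL24A1, FAM86B1 and ZBTB10 present in sh-POLR2B and TCHH and SBSN in sh-NC. The same pattern between the replicate numbers gave 8 genes and the crossed pairing 5, so mixed patterns were on average 0.812 times as frequent as the group pattern, past the 0.5 set beforehand as the mark of reads divided unstably between similar genes. The pattern thus also arises between libraries of the same group, and a switch by the knockdown is not shown for these genes. Such reads stay open as an explanation for ZBTB10 and COL24A1, which were fractional, and for MYLK2 and FAM86B1, which were whole within 0.02 reads but not within 0.0005. For the other 4, whole within 0.0005 reads in all libraries, the whole values count against it, and what produced the pattern there was not tested.

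ACTA2, TAGLN and CNN1, markers of contractile smooth muscle, were among the higher genes, CNN1 at 48.0 ± 0.593 in sh-NC and 121 ± 36.4 in sh-POLR2B (SD, n = 2 each; named after its values were seen). A hypothesis is that contractile genes rose as a set. With those 3 left out, 10 other contractile genes had a corrected median of 0.38, 7 of them positive, and ranked above other genes (camera p = 0.000465, or p = 0.0674 with an estimated correlation). Of these, TPM1 was already among the higher genes with the lowest p. Without it the other 9 had a corrected median of 0.24, 6 of them positive (camera p = 0.00245, or p = 0.0878 with an estimated correlation). ACTG2 had a corrected fold of 2.78 and MYL9 of 1.74, whereas SMTN was at 0.854 and MYLK at 0.826. As deposited, the sh-POLR2B libraries lay on opposite sides of sh-NC for MYLK (1143 and 4065 against 2293 and 2528). CALD1, at a corrected fold of 2.01, was high mainly in replicate 2 (628 and 2307 against 550 and 587). The set may thus be part of the difference, but its camera p was under 0.05 only with the preset correlation.

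The 4 libraries can be split into pairs in 3 ways, too few for a share under 0.05. The real split gave 11 lists past the threshold, as many being reached by 1 of the 3 splits, and the highest of the others was 7. The split by replicate number gave 4 genes past an adjusted p of 0.05 in limma and 1645 at an unadjusted p under 0.05, several times the 224 of the real split, which points to a structure of the samples other than the groups. With only 2 pairs and no batch in the labels, it is not shown that the replicate number marks it. After correction the order of these unadjusted counts turned, with 793 genes for the replicate numbers and 923 for the groups. Lists past the threshold were 5 for the replicate numbers and 11 for the groups as deposited, and 7 and 13 after correction. Genes past an adjusted p of 0.05 were then 3 for the replicate numbers and 0 for the groups.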
